A study of Mus musculus with 10 samples.

How the data were processed

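Total RNA from 5 papillary and 5 anaplastic mouse thyroid carcinomas was labelled with biotin and hybridised to Affymetrix whole-transcript arrays, per the labels' protocols. The deposited series table holds 35556 probe sets on 10 arrays with no missing value. The submitters' processing notes name Affymetrix Power Tools and limma without a version or a role. The background correction, normalization, summarisation and genome build are not given in the sources used here. The scale is not stated either; the deposited values, which run from 2.79 to 14.15 with array medians of 7.25 to 7.34, were read as normalized log2 intensities from their range, and they were tested as deposited. ATC replicate 5 had a wider distribution, with quartiles of 6.02 and 8.72 against 6.10 to 6.19 and 8.57 to 8.64 in the other arrays. It also had the lowest array weight (0.38). Detection above background is not given, so differences of dim genes may be compressed.

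Probe sets were named from the platform annotation given with the table: 21789 had 1 gene symbol, 1621 had several and 12146 had none here. Gene identifiers of 21698 probe sets matched the mouse gene table of assembly GRCm38.p6, which was used only for current names and for the chromosome and order of genes; no coordinates are given. Each gene was represented by the probe set with the highest mean over the 10 arrays, which left 19938 genes, 999 of them with several probe sets. For 0 genes did probe sets pass the threshold in both directions. Probe sets with several symbols or none named no gene.

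The groups and replicate numbers were taken from the sample titles. The contrast ATC minus PTC was fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, without covariates, block or filter on dim genes, and p-values were adjusted by the Benjamini-Hochberg method over all 19938 genes at a threshold of 0.05. Intervals are 95% intervals from the same fit. On simulated data with the spread of these arrays, the procedure recovered 50% of 50 genes changed by 0.5 log2 units, 84% of 50 changed by 1, 98% of 50 changed by 2 and 100% of 50 changed by 3, and 6.21% of its 177 calls were false. For lists, 5 of 5 raised lists were found and 0 of 25 unchanged lists were called. The simulated genes were independent and the lists random, whereas members of the real lists were correlated (estimated correlation 0.85 in the mitosis list). The simulation therefore does not show how often correlated lists are falsely called.

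The design, the lists, the naming rule and most alternatives were fixed before the data were examined. There were 15 gene lists and 15 lists of cell type markers, with 485 members, of which 450 were matched to a gene; the others are not analysed here. Lists were tested with camera at its preset correlation of 0.01, with adjustment over all 30 lists, and again with the estimated correlation, for which statmod 1.5.0 was also loaded. The self-contained test fry was run beside it. The rule named Braf and Cdkn2a among others in any case, the 10 largest rises and 10 largest falls among genes past the threshold with separate groups, the 3 members of each list with the largest absolute difference, a few classical members of some lists, and sex-linked genes; 126 genes were named, and members without a probe set of 1 symbol are not analysed here. Predicted genes, clone names and olfactory and vomeronasal receptors were passed over among the largest changes.

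Alternatives were a replicate block, the mean of a gene's probe sets, all probe sets, 2 filters on dim genes, quantile normalization once more, centring of each array on its median, a variance trend with robust estimation, array weights, covariates for Y-linked genes and for skeletal muscle markers, and each array left out in turn. A covariate for the parathyroid markers and a fit without ATC replicate 2 and PTC replicate 5 were chosen after seeing the data. Another 9 lists used in the closing section were also chosen after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for tables and figures.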

Results

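RNA from 10 mouse thyroid tumours was measured on Affymetrix whole-transcript expression arrays, 1 array per tumour. The 5 papillary thyroid carcinomas (PTC) came from mice in which a tamoxifen-inducible Cre recombinase, driven by the thyroid peroxidase promoter, switches on a mutant Braf allele in thyroid cells. The 5 anaplastic thyroid carcinomas (ATC) came from mice of the same kind that also lacked p53. The comparison therefore asks how poorly differentiated tumours without p53 differ from differentiated tumours that share the Braf mutation, and tumour type and p53 genotype changed together. The labels call the tumours biological replicates and do not say whether each came from a different animal, so the spread between tumours is the only error measured. All values are log2 probe set intensities, differences are ATC minus PTC, means are given ± SD with n = 5 tumours per group, and the number of arrays limits the precision. Genes named only to spell out a count of 5 or fewer members of a list were chosen after their values were seen.

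The 2 tumour types differed in a large part of the transcriptome. Of 19938 genes, 2297 were higher and 1937 lower in ATC at an adjusted p under 0.05 (limma, Benjamini-Hochberg), together 4234 genes or 21.2%. Of these, 361 were higher and 489 lower by at least 1 log2 unit, and at least 2 log2 units separated 52 genes that rose and 115 that fell. All 5 ATC values lay above all 5 PTC values for 1820 genes (9.13%) and below them for 1544 (7.74%), against 0.794% of genes expected by chance for both directions together. The first principal component held 56.8% of the variance and separated the types, with ATC replicate 2 (score 11.99) nearest to the PTC arrays (−36.5 to −28.8). Arrays correlated at 0.980 to 0.993 across genes within PTC, 0.970 to 0.981 within ATC and 0.927 to 0.974 between the types. ATC tumours varied more among themselves: 68.6% of genes had the larger SD in ATC, and the median SD was 0.17 in ATC and 0.13 in PTC. Without ATC replicate 2, 4084 genes passed, and 3772 of them were among the 4234.

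Cdkn2a, which encodes the Ink4a and Arf tumour suppressors, was 2.28-fold higher in ATC (probe set 10514340, 6.71 ± 0.09 in PTC and 7.90 ± 0.13 in ATC, difference 1.19, 95% interval 1.01 to 1.36, adjusted p = 1.82e-05). All 5 ATC tumours lay above all 5 PTC tumours. Braf, the oncogene that both models share, was at 10.005 ± 0.08 in PTC and 9.92 ± 0.21 in ATC (probe set 10544219, difference −0.08, adjusted p = 0.632). The level of the deleted gene itself is not analysed here, so the genotype in the labels was not checked from the arrays.

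The largest rises among genes with separate groups included several macrophage surface proteins. Vsig4, a complement receptor of tissue macrophages, went from 7.02 ± 0.88 to 11.998 ± 0.51, a 31.6-fold difference (adjusted p = 3.32e-05). Cd163, the scavenger receptor for haemoglobin complexes, rose by 3.47 (SE 0.35), the hyaluronan receptor Lyve1 by 3.29 (SE 0.33), and F13a1, the A chain of a coagulation factor that macrophages also make, by 3.68 (SE 0.28). Cdh2, which encodes N-cadherin, rose by 3.12 from 6.49 ± 0.25 to 9.61 ± 0.40 and had the smallest p of these (adjusted p = 1.25e-05). The other large rises were those of Nrn1 (3.70), Hal (3.61), the growth factor gene Bmp2 (3.20), the neurofilament gene Nefm (3.13) and Dynap (3.10). Nefm and Dynap were spread widely in ATC, with SDs of 1.75 and 1.65. Adjusted p-values of these 10 genes ran from 1.25e-05 to 0.00642.

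The largest falls among genes with separate groups included genes known from secretory epithelia. Pappa2, a protease of insulin-like growth factor binding proteins, fell from 11.65 ± 0.46 to 7.31 ± 1.29, a 20.2-fold difference (adjusted p = 0.000321). Lamp3, a lysosomal membrane protein of surfactant-making lung cells and mature dendritic cells, fell by 4.31 (SE 0.65). The lung chemokine gene Cxcl15 fell by 4.03 (SE 0.49), and Cyp2f2, a cytochrome of airway club cells, fell by 3.78 (SE 0.61). Chil1 (−3.67), Gabrp (−3.61), Dcpp3 (−3.58), Tspan1 (−3.41), Oit1 (−3.38) and Mal2 (−3.34) completed the set. Dcpp3 has close paralogs, and its probe set was not checked for signal from them. Adjusted p-values of these 10 genes ran from 3.27e-05 to 0.00656.

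**Figure D1:**
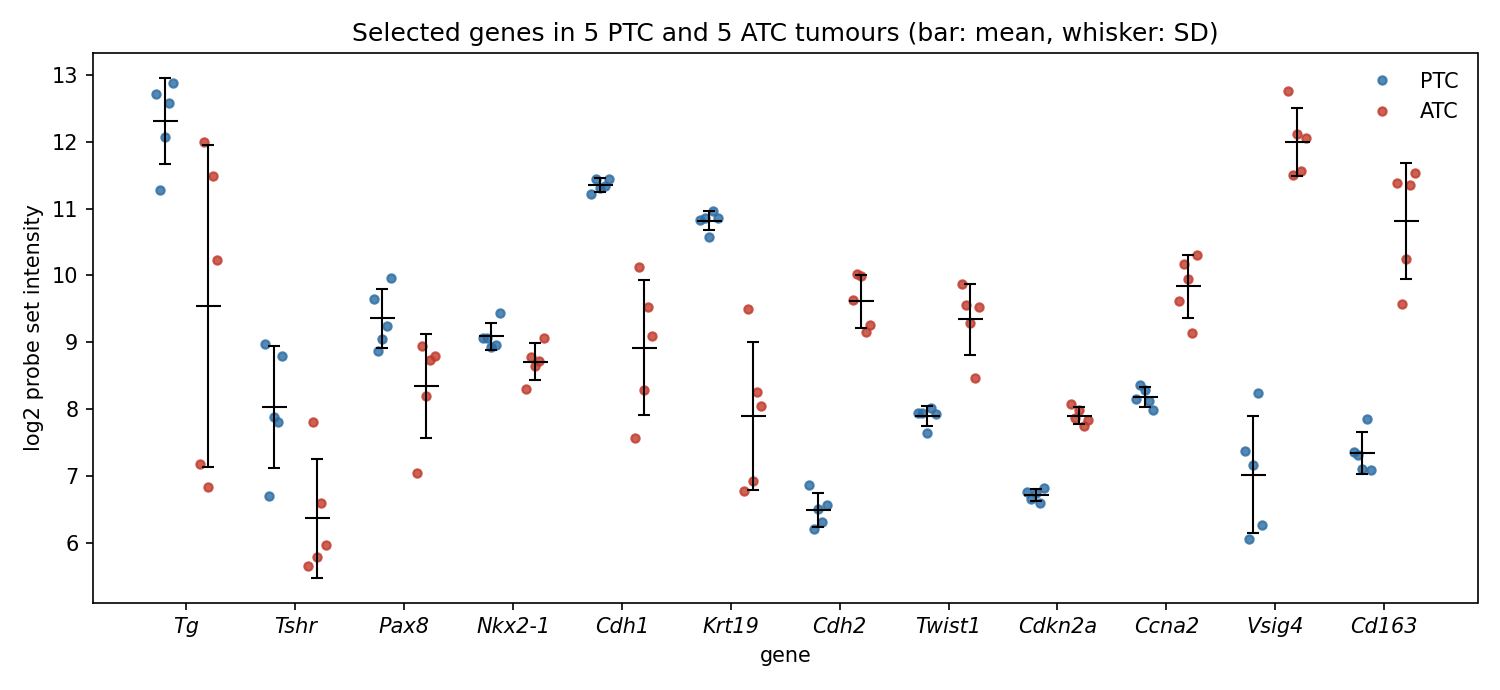
Log2 probe set intensity (vertical axis) of 12 genes (horizontal axis) in each PTC tumour (blue) and ATC tumour (red), with the mean and SD of 5 tumours as bar and whisker. Cdkn2a, Cdh2, Vsig4 and Cd163 lay higher in every ATC tumour, Cdh1 and Krt19 lay lower in every ATC tumour, and Tg in ATC was spread from 6.84 to 12.001.

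Genes of thyroid hormone production and thyroid identity were lower in ATC as a group. Of 21 measured members, 0 rose, 8 fell and 13 did not pass over all genes, and 12 fell when adjusted over the list alone. The median difference was −0.46 (camera adjusted p = 6.47e-07, and adjusted p = 0.216 with an estimated correlation). Iyd, the iodotyrosine deiodinase, fell by 2.33 (SE 0.67, adjusted p = 0.0299), the anion transporter gene Slc26a7 fell by 1.96 (SE 0.54, adjusted p = 0.0235) and the thyrotropin receptor gene Tshr fell by 1.67 (SE 0.48, adjusted p = 0.0295). Thyroglobulin, Tg, was at 12.31 ± 0.65 in PTC and 9.54 ± 2.41 in ATC (difference −2.76, adjusted p = 0.0583), with ATC tumours at 7.17, 12.001, 6.84, 11.48 and 10.23. The lineage transcription factor genes differed by −1.01 for Pax8 (adjusted p = 0.0564), −0.38 for Nkx2-1 (adjusted p = 0.0745) and −0.23 for Foxe1 (adjusted p = 0.230), and the iodide transporter gene Slc5a5 by −0.46 (adjusted p = 0.264). Parathyroid hormone, Pth, ranged from 4.38 to 12.66 over the tumours, with 9.89 ± 3.39 in PTC and 7.05 ± 2.97 in ATC. The Tshr call ended without PTC replicate 1, 3, 4 or 5 or ATC replicate 1, 3 or 5 (differences −1.72 to −1.43, adjusted p 0.0516 to 0.0736). That of Iyd ended without PTC replicate 1, 4 or 5 or ATC replicate 1, 3 or 5 (−2.29 to −1.94, adjusted p 0.0594 to 0.0699), and that of Slc26a7 without PTC replicate 1, 4 or 5 or ATC replicate 1 or 5 (−1.93 to −1.65, adjusted p 0.0511 to 0.0601). Tg passed without ATC replicate 2 or 4 (−3.38 and −3.25, adjusted p = 0.0194 and 0.0337), Pax8 without ATC replicate 2 (−1.17, adjusted p = 0.0391) and Nkx2-1 without ATC replicate 5 (−0.47, adjusted p = 0.0264).

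Epithelial junction and keratin genes fell in ATC almost throughout the list. Of 23 members, 20 fell, 0 rose and 3 did not pass, over all genes and adjusted over the list alone, with a median of −1.25 (camera adjusted p = 1.27e-15, and adjusted p = 0.184 with an estimated correlation). Krt7 fell by 3.14 (SE 0.59), Krt19 fell by 2.92 (SE 0.42) and the adhesion molecule gene Epcam fell by 2.73 (SE 0.61), with adjusted p-values of 0.0035, 0.00085 and 0.00838. Cdh1, which encodes E-cadherin, went from 11.35 ± 0.10 to 8.92 ± 1.01, a 5.4-fold fall (adjusted p = 0.00136). The ATC tumours varied here, and ATC replicate 2 kept the highest Cdh1 of them at 10.13.

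Mesenchymal genes rose. Of 19 members, 11 rose, 1 fell and 7 did not pass, over all genes and adjusted over the list alone, with a median of 0.60 (camera adjusted p = 1.28e-06, and adjusted p = 0.134 with an estimated correlation). Besides Cdh2 (3.12), the transcription factor genes Prrx1 and Twist1 rose by 1.52 (SE 0.19) and 1.45 (SE 0.22), with adjusted p-values of 0.000374 and 0.000953. Vim, the intermediate filament of mesenchymal cells, was already high in PTC (12.29 ± 0.14) and rose by 0.60 (SE 0.09, adjusted p = 0.00109). The member that fell was Cdh11 (−1.09), a cadherin of mesenchymal cells. The list mean was 9.91 ± 0.09 in PTC and 10.60 ± 0.10 in ATC.

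Cell division genes rose. In the mitosis list 27 of 29 members rose, 0 fell and 2 did not pass (28 rose adjusted over the list alone), with a median of 1.05 (camera adjusted p = 1.27e-15, and adjusted p = 0.353 with an estimated correlation). The cyclin gene Ccna2 rose by 1.66 (SE 0.19), the spindle checkpoint kinase gene Bub1 by 1.62 (SE 0.32) and the spindle assembly factor gene Tpx2 by 1.62 (SE 0.24), with adjusted p-values of 0.000288, 0.00425 and 0.00102. ATC replicate 4 had the lowest Bub1 of the ATC tumours, 7.63 against 9.06 to 9.60 in the others. Mki67 went from 8.52 ± 0.06 to 9.31 ± 0.58 (difference 0.78, adjusted p = 0.0303). In the DNA replication and repair list 19 of 29 members rose, 0 fell and 10 did not pass (22 rose adjusted over the list alone), with a median of 0.50 (camera adjusted p = 6.94e-11, and adjusted p = 0.335 with an estimated correlation). Rfc4 rose by 0.97 (SE 0.14, adjusted p = 0.000925), the checkpoint kinase gene Chek1 by 0.92 (SE 0.18, adjusted p = 0.00482) and the ribonucleotide reductase gene Rrm2 by 0.88 (SE 0.24, adjusted p = 0.0242). The Mki67 call ended without ATC replicate 2 or 5 or any of the 5 PTC arrays (differences 0.61 to 0.80, adjusted p 0.0538 to 0.066), and the Rrm2 call without PTC replicate 1 or 5 or ATC replicate 3 or 5 (0.73 to 0.87, adjusted p 0.051 to 0.0566).

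Genes known as direct targets of p53 were lower in the tumours without it. Of 26 members, 12 fell, 1 rose and 13 did not pass (13 fell and 3 rose adjusted over the list alone), with a median of −0.23 (camera adjusted p = 0.0142, and adjusted p = 0.134 with an estimated correlation). The antiproliferative gene Btg2 fell by 1.17 (SE 0.18), Perp, a desmosome protein gene, fell by 1.16 (SE 0.25), and Trp53inp1 fell by 1.03 (SE 0.21), with adjusted p-values of 0.00106, 0.0072 and 0.00484. Ccng1 fell by 0.47 (adjusted p = 0.00252) and Mdm2, which encodes the ubiquitin ligase of p53, differed by −0.18 (adjusted p = 0.0541). The member that rose was the apoptosome gene Apaf1 (0.55). The list mean was 8.69 ± 0.03 in PTC and 8.47 ± 0.04 in ATC.

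Transcripts downstream of the MAPK pathway moved both ways, with 3 of 19 members up, 3 down and 13 not passing, the same counts adjusted over the list alone, and a median of 0.28 (camera adjusted p = 0.118). Fosl1 and Myc, which encode transcription factors, rose by 1.57 (SE 0.23) and 1.35 (SE 0.20), with adjusted p-values of 0.00085 and 0.000981, and Etv5 rose by 0.45. Epha4 fell by 1.19 (SE 0.21, adjusted p = 0.00229), Phlda1 fell by 0.58 and Spred1 fell by 0.45. The feedback genes Dusp6 and Spry4 differed by −0.08 (adjusted p = 0.828) and 0.28 (adjusted p = 0.491). The list passed without ATC replicate 2 and PTC replicate 5, a fit chosen after the data were seen (median 0.39, camera adjusted p = 0.046, and adjusted p = 0.660 with an estimated correlation), and its median was 0.18 without ATC replicate 3 (adjusted p = 0.276).

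Invasion, metabolic, secretory and ciliary genes were measured as 5 further lists, of which the unfolded protein list alone passed. Among 18 invasion protease genes 3 rose and 1 fell (3 and 2 adjusted over the list alone; median 0.16, camera adjusted p = 0.418), and the median was 0.024 without ATC replicate 3 and 0.010 without ATC replicate 5 (adjusted p = 0.378 and 0.953). Plau, the urokinase gene, rose by 1.38 (SE 0.21, adjusted p = 0.00109), the heparanase gene Hpse by 1.19 (SE 0.25, adjusted p = 0.00567) and Ctsl by 0.66, whereas Mmp12 fell by 1.49 (SE 0.42, adjusted p = 0.0264). Of 20 hypoxia and glycolysis genes 6 rose and 0 fell, also adjusted over the list alone (median 0.29, camera adjusted p = 0.0557), among them Egln3 (1.56, adjusted p = 0.013), Pdk1 (0.77, adjusted p = 0.012) and Pgam1 (0.66, adjusted p = 0.0247). Of 21 oxidative phosphorylation genes 5 rose and 2 fell, also adjusted over the list alone (median 0.13, camera adjusted p = 0.0932), with Sdhb at 0.58, Cox5a at 0.44 and Sdha at −0.42 (adjusted p = 0.00106, 0.0188 and 0.0313). Of 18 unfolded protein and secretory genes 2 fell and 0 rose (1 fell adjusted over the list alone; median −0.16, camera adjusted p = 0.0345, and adjusted p = 0.607 with an estimated correlation), namely Xbp1 (−0.81, adjusted p = 0.00109) and Calr (−0.42, adjusted p = 0.0389), and Pdia6 differed by −0.41 (adjusted p = 0.0557). Of 19 ciliary genes 2 rose and 4 fell (3 and 5 adjusted over the list alone; median −0.10, camera adjusted p = 0.390), with Ift74 at 0.76, Ift81 at −0.68 and Tekt1 at −0.58 (adjusted p = 0.00971, 0.0111 and 0.00673).

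Several of these calls lay close to the threshold and ended when an array was left out. The Mmp12 call ended without PTC replicate 2, 3 or 4 or ATC replicate 1 (differences −1.52 to −1.34, adjusted p 0.0503 to 0.0641) and that of Pgam1 without PTC replicate 3, 4 or 5 or ATC replicate 5 (0.60 to 0.64, adjusted p 0.0512 to 0.0591). The Sdha call ended without PTC replicate 3, 4 or 5 or ATC replicate 1, 3 or 4 (−0.42 to −0.34, adjusted p 0.0579 to 0.0723) and that of Calr without PTC replicate 1, 2, 4 or 5 or ATC replicate 1 or 4 (−0.45 to −0.31, adjusted p 0.053 to 0.0856). Pdia6 passed without ATC replicate 3 or 5 (−0.49 to −0.48, adjusted p 0.0304 to 0.0365). The hypoxia and glycolysis list passed without PTC replicate 2 or ATC replicate 1, 2 or 4 (medians 0.33 to 0.40, camera adjusted p 0.0103 to 0.0354) and with a variance trend and robust estimation (0.29, adjusted p = 0.049), but its median was 0.15 without ATC replicate 3 (adjusted p = 0.238) and 0.17 with the parathyroid covariate (adjusted p = 0.208). The oxidative phosphorylation list passed without ATC replicate 1 or 4 (0.16 for each, adjusted p 0.0364 to 0.0433) and with the muscle covariate (0.17, adjusted p = 0.047), but its median was 0.065 without ATC replicate 5 (adjusted p = 0.360) and 0.059 with quantile normalization once more (adjusted p = 0.554). The unfolded protein list no longer passed without PTC replicate 2 or 4 or ATC replicate 4 (−0.16 to −0.13, adjusted p 0.0623 to 0.118) or with the parathyroid covariate (−0.12, adjusted p = 0.0676). With an estimated correlation, the hypoxia and oxidative phosphorylation lists passed in 0 of these fits (adjusted p 0.556 to 0.726).

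Immune signalling genes also went both ways. Of 16 interferon response genes 2 rose and 1 fell, also adjusted over the list alone (median 0.08, camera adjusted p = 0.577). Ifit2 rose by 1.40 (SE 0.20, adjusted p = 0.00083) and the T cell chemokine gene Cxcl10 by 1.13 (SE 0.28, adjusted p = 0.0155), Ifih1 fell by 0.52, and Rsad2 differed by 0.85 (adjusted p = 0.172). Of 13 antigen presentation genes 3 fell and 0 rose, also adjusted over the list alone (median −0.33, camera adjusted p = 0.0128, and adjusted p = 0.607 with an estimated correlation). These were the immunoproteasome gene Psmb9 (−0.43, adjusted p = 0.0345), Tap1 (−0.38) and Tapbp (−0.33), and the class II genes Cd74 and Ciita differed by −0.40 (adjusted p = 0.278) and −0.39 (adjusted p = 0.130). Of 21 cytokine and chemokine genes 3 rose and 6 fell (4 and 7 adjusted over the list alone; median −0.10, camera adjusted p = 0.833). The monocyte chemoattractants Ccl2 and Ccl7 rose by 2.05 (SE 0.28, adjusted p = 0.000665) and 1.67, and Csf1, the macrophage growth factor, by 1.85, whereas Csf2 fell by 2.00 (SE 0.35, adjusted p = 0.00222) and the neutrophil chemokine gene Cxcl5 fell by 3.06 (SE 0.82, adjusted p = 0.0217). The Psmb9 call ended without PTC replicate 2, 3, 4 or 5 or ATC replicate 1, 3 or 4 (differences −0.46 to −0.37, adjusted p 0.0531 to 0.0829) and that of Cxcl5 without PTC replicate 1 (−2.60, adjusted p = 0.053). Ciita passed without ATC replicate 2 (−0.55, adjusted p = 0.00692), and the antigen presentation list no longer passed without ATC replicate 3 (median −0.22, camera adjusted p = 0.0603).

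**Figure D2:**
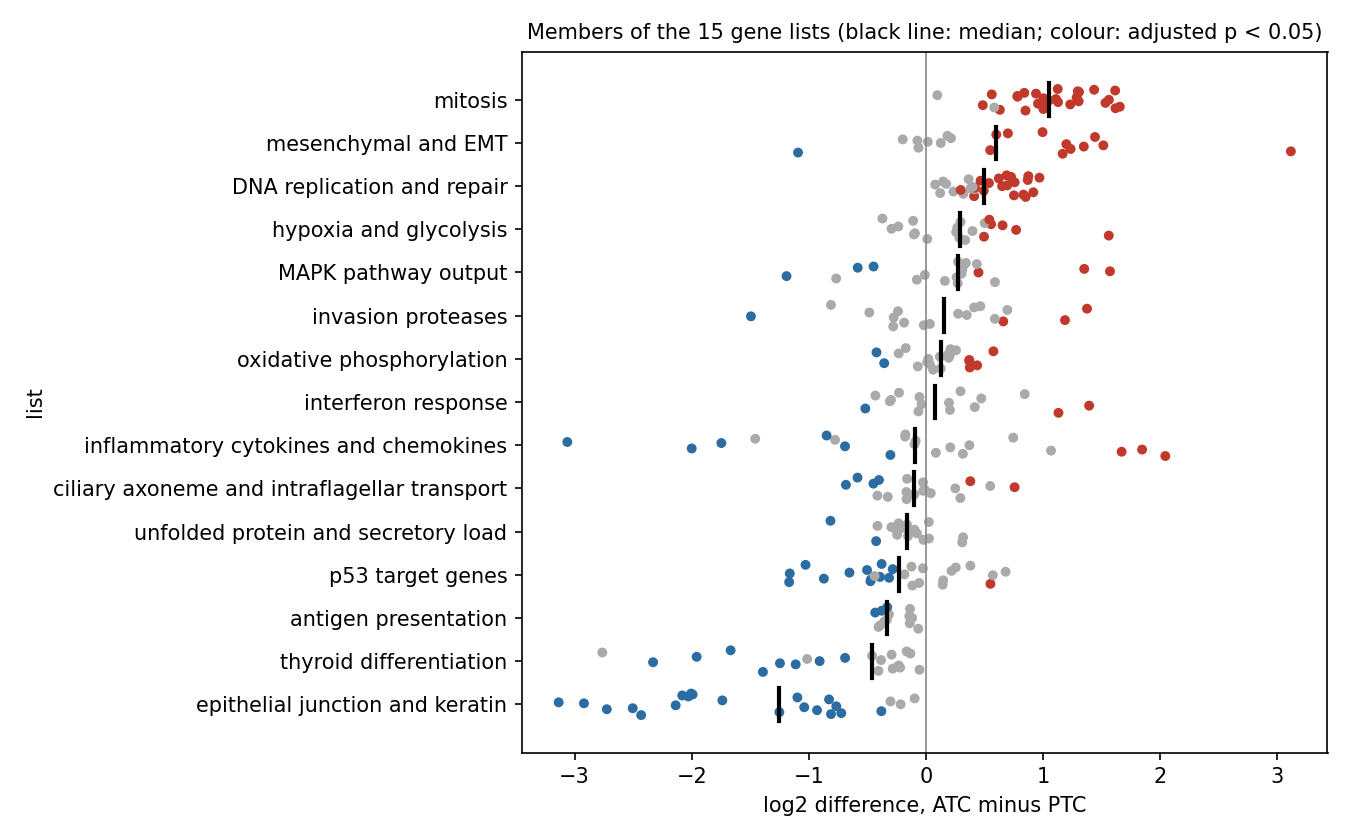
Log2 difference, ATC minus PTC (horizontal axis), of each measured member of the 15 gene lists (vertical axis), red for genes higher and blue for genes lower in ATC at an adjusted p under 0.05 and grey for the others, with the list median as a black line. The mitosis median of 1.05 was the highest and the epithelial median of −1.25 the lowest.

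Among markers of cell types that tumour pieces can hold, those of macrophages rose most. Of 14 members 13 rose, 0 fell and 1 did not pass (14 rose adjusted over the list alone), with a median of 1.34 (camera adjusted p = 3.49e-13, and adjusted p = 0.134 with an estimated correlation). The scavenger receptor gene Msr1 rose by 1.79 (SE 0.22), the integrin gene Itgam by 1.74 (SE 0.21) and the complement gene C1qa by 1.58 (SE 0.22), with adjusted p-values of 0.000342, 0.00032 and 0.000706. The list mean was 9.32 ± 0.22 in PTC and 10.56 ± 0.22 in ATC. Of 8 mast cell markers 3 rose and 0 fell, also adjusted over the list alone (median 0.25, camera adjusted p = 0.0344, and adjusted p = 0.379 with an estimated correlation), namely Cpa3 (1.96, adjusted p = 0.0397), Fcer1a (0.93, adjusted p = 0.0108) and Tpsb2 (0.25), and Mcpt4 differed by 0.40 (adjusted p = 0.535). Of 12 neutrophil markers 1 rose, Clec4d (1.08), and 0 fell, also adjusted over the list alone (median −0.04, camera adjusted p = 0.612), with Lcn2 at −2.35 (adjusted p = 0.0627), S100a9 at −1.35 (adjusted p = 0.112) and Cxcr2 at −1.29 (adjusted p = 0.131). Within PTC, Lcn2 varied little (SD 0.08) while S100a9 and Cxcr2 varied widely (SDs 1.22 and 1.25), and the cell source of Lcn2 was not tested. The Cpa3 call ended without any PTC array or without ATC replicate 1, 2 or 4 (differences 1.55 to 2.04, adjusted p 0.064 to 0.0893), and the mast cell list no longer passed without PTC replicate 5 or ATC replicate 2 (medians 0.24 to 0.26, camera adjusted p 0.0553 to 0.0826), without ATC replicate 2 and PTC replicate 5 together (0.21, adjusted p = 0.117), or with the 3 members left by the milder filter on dim genes (0.24, adjusted p = 0.388). Lcn2 passed without ATC replicate 2 or 4 (−2.84 and −2.74, adjusted p 0.0257 to 0.0405), and S100a9 and Cxcr2 passed without PTC replicate 5 (−1.79 for each, adjusted p = 0.0214 and 0.0155).

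The T cell and the B and plasma cell lists were lower in ATC by camera with its preset correlation. Of 11 T cell markers 4 fell and 0 rose, also adjusted over the list alone (median −0.23, camera adjusted p = 0.00113, and adjusted p = 0.318 with an estimated correlation). Cd2 fell by 1.57 (SE 0.21, adjusted p = 0.000503), Cd3g fell by 1.34 (SE 0.32, adjusted p = 0.0127), the costimulatory receptor gene Cd28 fell by 0.88 (SE 0.12, adjusted p = 0.000717) and Cd3e fell by 0.43. Of 11 B and plasma cell markers 4 fell and 0 rose, also adjusted over the list alone (median −0.23, camera adjusted p = 0.0128, and adjusted p = 0.607 with an estimated correlation). These were Jchain (−2.22, adjusted p = 0.0145), Fcer2a (−1.07, adjusted p = 0.00413), Cd79b (−0.78, adjusted p = 0.00226) and Blk (−0.31). The B cell list no longer passed without PTC replicate 2, which had the highest list mean (median −0.11, camera adjusted p = 0.0884). Of 9 natural killer and cytotoxic markers 1 rose and 2 fell, also adjusted over the list alone, with a median of 0.06, a mean of −0.03 and an upward camera direction (adjusted p = 0.944). Klrk1 fell by 0.90 (adjusted p = 0.00309) and the granzyme gene Gzmb rose by 0.51 (adjusted p = 0.0116). Nkg7 fell by 0.20 (adjusted p = 0.048), a call that ended without PTC replicate 1, 2, 3 or 4 or ATC replicate 1, 2, 3 or 5 (−0.21 to −0.18, adjusted p 0.0742 to 0.117).

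Among stromal markers the fibroblast list did not pass and the endothelial list was lower in ATC. Of 17 fibroblast and matrix genes 4 fell and 0 rose, also adjusted over the list alone (median −0.20, camera adjusted p = 0.0681), namely the proteoglycan genes Lum (−2.07, SE 0.35, adjusted p = 0.00177) and Dcn (−1.35, SE 0.19, adjusted p = 0.000648), Fap (−0.91) and Postn (−0.73). The receptor gene Pdgfra differed by 1.17 (adjusted p = 0.0848), with an SD of 0.06 in PTC and 1.16 in ATC. Of 12 endothelial markers 2 fell and 0 rose (4 fell adjusted over the list alone; median −0.18, camera adjusted p = 0.0345, and adjusted p = 0.607 with an estimated correlation), namely Tek (−0.67, adjusted p = 0.0161) and Pecam1 (−0.40, adjusted p = 0.049998), and Kdr differed by −0.67 (adjusted p = 0.0514). The Pecam1 call ended without any PTC array or without ATC replicate 1 or 3 (differences −0.44 to −0.31, adjusted p 0.0603 to 0.117), and the endothelial list no longer passed without PTC replicate 1 or 5 or ATC replicate 1 or 3 (medians −0.19 to −0.11, camera adjusted p 0.0548 to 0.0798). Pdgfra passed without ATC replicate 2 (1.57, adjusted p = 0.0056) and Kdr without PTC replicate 2 or ATC replicate 2 (−0.82 and −0.81, adjusted p 0.0196 to 0.0218). The fibroblast list passed without ATC replicate 5 (median −0.34, camera adjusted p = 0.000901), and the other left-out arrays gave medians from −0.27 to −0.05, the smallest without ATC replicate 4 (adjusted p = 0.118). It also passed without genes below the median brightness (−0.20, adjusted p = 0.0281), with quantile normalization once more (−0.24, 0.0244), centring (−0.16, 0.0339), array weights (−0.10, 0.024) and the parathyroid covariate (−0.09, 0.0415), whereas the muscle covariate gave −0.08 (0.114). With an estimated correlation it passed in 0 of these fits (adjusted p 0.275 to 0.640). With array weights the endothelial list no longer passed (−0.12, adjusted p = 0.138).

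Markers of C cells, parathyroid, fat, muscle, cartilage, nerve sheath and red cells gave no list that passed with all 10 tumours. Of 6 C cell markers 1 fell, Scg2 (−1.06, adjusted p = 0.0121), with Chga at −1.32 (adjusted p = 0.215) and Gfra4 at 0.29 (adjusted p = 0.478; list median −0.04, camera adjusted p = 0.501). The 2 parathyroid markers were Pth (−2.83, adjusted p = 0.283) and Casr (−0.40, adjusted p = 0.306; list median −1.62, camera adjusted p = 0.393). Without ATC replicate 2 and PTC replicate 5, a fit chosen after the data were seen, Pth differed by −5.44 (adjusted p = 0.00258) and the list median was −3.04 (camera adjusted p = 0.046, and adjusted p = 0.531 with an estimated correlation). These 2 arrays held the highest Pth in ATC (11.975) and the lowest in PTC (4.38). Leaving them out therefore widens the Pth difference by construction, and this fit is no evidence for a parathyroid difference. Of 9 adipocyte markers 0 passed (median −0.06, camera adjusted p = 0.612), with Adipoq at −0.42, Ucp1 at 0.36 and Lep at −0.15. Of 12 muscle markers 0 passed (median −0.20, camera adjusted p = 0.362), with Myh4 at −1.05, Atp2a1 at −0.63 and Myh1 at −0.54. Of 9 cartilage and trachea markers 2 fell (median −0.10, camera adjusted p = 0.212), the matrix gene Comp (−1.16, adjusted p = 0.000342) and the secretoglobin gene Scgb3a2 (−0.70, adjusted p = 0.0226), with Scgb1a1 at 0.20 (adjusted p = 0.360). Of 3 nerve sheath markers the myelin gene Mbp fell by 0.32 (adjusted p = 0.0084), with Pmp22 at −0.13 and Sox10 at −0.03 (list median −0.13, camera adjusted p = 0.362). Of 3 red cell markers 0 passed (median −0.07, camera adjusted p = 0.597), with Epb42 at −0.17, Slc4a1 at −0.07 and Alas2 at 0.00 (adjusted p = 0.999). The counts adjusted over each list alone were the same for these 7 lists. The Scgb3a2 call ended without PTC replicate 3 or ATC replicate 3 or 5 (−0.68 to −0.60, adjusted p 0.0502 to 0.0535), and Ucp1 passed without ATC replicate 5 (0.45, adjusted p = 0.0145).

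**Figure D3:**
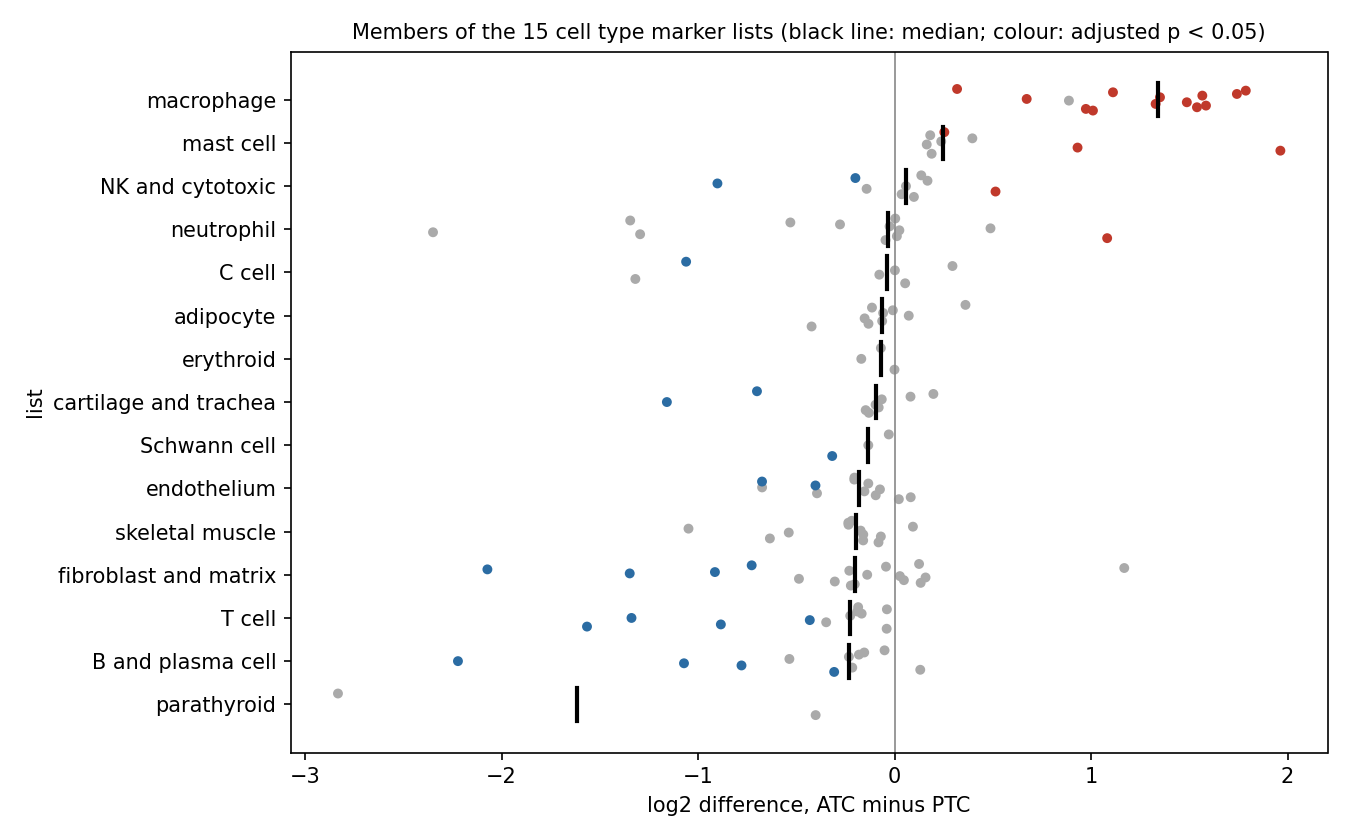
Log2 difference, ATC minus PTC (horizontal axis), of each measured member of the 15 cell type marker lists (vertical axis), red for genes higher and blue for genes lower in ATC at an adjusted p under 0.05 and grey for the others, with the list median as a black line. The macrophage median of 1.34 was the highest of the 15.

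Over all 30 lists, 13 passed the camera test with its preset correlation, 5 upward and 8 downward, and 0 of these 13 passed camera with the correlation estimated from the arrays, 5 of them at an unadjusted p under 0.05. By fry, which tests whether a list's genes move one way without comparing them with other genes, 10 of the 13 passed. Of 100 splits of the 10 arrays into 5 and 5, 17 gave at least 13 lists past camera with the preset correlation. These include the real split and splits that exchange only 1 tumour of each type, which keep most of the real difference. They also include splits that exchange 2 tumours of each type, the most even mixture, with 14 or 15 lists. Some medians depended on how many dim members were kept. Without genes below the median brightness, the median was −1.18 for the 10 thyroid genes left, −1.999 for 18 epithelial genes, −0.38 for 21 p53 targets, −0.30 for 8 endothelial genes, −1.50 for 2 B and plasma cell genes and −0.91 for 6 neutrophil genes (camera adjusted p = 0.394). Without the dimmest genes by the milder filter it was −1.01 for 15 thyroid genes, −0.66 for 6 T cell genes and −0.28 for 9 neutrophil genes, and the B and plasma cell list no longer passed (−0.21, camera adjusted p = 0.065).

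The X-inactivation transcript and Y-linked transcripts were measured in all 10 tumours, with no array known to be from a female animal for reference. Xist was at 5.93 ± 0.50 in PTC and 5.62 ± 0.33 in ATC, the Y-linked gene Eif2s3y at 9.70 ± 0.29 and 9.85 ± 0.22, and Uty at 9.30 ± 0.12 and 9.35 ± 0.14. Kdm5d, also Y-linked, was at 9.32 ± 0.07 in PTC and 8.89 ± 0.35 in ATC (adjusted p = 0.0535), and it passed without ATC replicate 4 or 5 (−0.54 to −0.50, adjusted p 0.0122 to 0.0362).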

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

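In this part, both tests of ATC replicate 2 were set down before their results were seen.

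In 22 of 312 groups of 5 values, 1 tumour lay far from the other 4, measured as its gap to the nearest of them over the whole range; chance gives about 1 in 20, or 15.6 here. PTC replicate 5 accounted for 10 of them. It was lowest in PTC for Oit1 (0.712, 9.15 against 9.97 or more), Cox5a (0.834), Ift74 (0.815), Msr1 (0.832, 9.08 against 10.17 or more), Klrk1 (0.741) and Ccng1 (0.811). It was highest for Myc (0.712), Comp (0.805), Nkx2-1 (0.729, 9.43 against 9.06 or less) and the mean of the cartilage and trachea list (0.766). Among the other PTC tumours, replicate 1 was lowest for Mal2 (0.772) and highest for the mesenchymal list mean (0.786), replicate 2 was highest for Btg2 (0.717) and the B and plasma cell list mean (0.89, 7.82 against 7.08 or less), and replicate 3 was lowest for Twist1 (0.753).

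In ATC, replicate 4 was lowest for the mitotic genes Bub1 (0.727) and Tpx2 (0.745, 8.24 against 9.39 or more), and replicate 5 was highest for Ift81 (0.74) and lowest for Cd79b (0.924). Replicate 2 was highest for Tek (0.764), Chga (0.813, 8.92 against 7.35 or less) and the T cell list mean (0.718).

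ATC replicate 2 also lay nearest to the PTC tumours on the first principal component. A mislabelled PTC tumour is argued against, since 3 of 3 measures lay above all 5 PTC tumours: Cdkn2a at 7.87 against at most 6.82, the mitosis list mean at 9.08 against 7.69 and the macrophage list mean at 10.50 against 9.49. Papillary or other thyroid tissue mixed into the piece may account for its position. The 100 genes with the largest falls in the other ATC tumours implied a PTC-like share of 28.4% (95% bootstrap interval 24.5 to 32.4) and the 100 with the largest rises 36.7% (24.5 to 44.6), a difference of −8.37 percentage points. The intervals resample genes and not tumours. The 3 measures of ATC replicate 2 also lay within the range of the other ATC tumours. That range was 7.74 to 8.07 for Cdkn2a, 7.86 to 9.15 for the mitosis mean and 10.21 to 10.81 for the macrophage mean. A less advanced anaplastic tumour could also lie nearest to PTC and was not tested.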

How the results depend on the processing

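The 23 alternatives moved the count of 4234 genes to between 3097 (parathyroid covariate) and 4812 (all probe sets, counted as probe sets), and the counts by direction, by size and of lists stayed within 1.5 times throughout. Of 126 named genes, 87 passed; all 87 kept their sign in every alternative that could test them, and 66 passed in every one. The thyroid, p53 target, mitosis, replication, mesenchymal, epithelial and macrophage lists passed camera in every alternative at its preset correlation; with an estimated correlation 0 of these 7 passed (adjusted p 0.134 to 0.353). The parathyroid covariate, chosen after the data were seen, as was the fit without ATC replicate 2 and PTC replicate 5, ended 16 calls of named genes, among them Iyd, Slc26a7 and Tshr. Over all alternatives, values of named genes lost a call 144 times and gained one 58 times, and lists 16 times each; with an estimated correlation 0 of the 16 gained list calls held (adjusted p 0.275 to 0.726). The fit without those 2 arrays ended 10 calls, Ift81 (adjusted p = 0.0507) and Gzmb (0.0509) among them, the muscle covariate 6, all probe sets and centring 5 each, array weights 4, the Y-linked covariate 3, the variance trend 2 and quantile normalization 1. The cause was not tested. Besides Iyd, Slc26a7 and Tshr, the parathyroid covariate ended the calls of Cxcl10 (0.98, adjusted p = 0.0632), Jchain (−1.79, 0.0612) and Tek (−0.64, 0.0551), which kept theirs without any single array. With the replicate number as a replicate block, 3762 genes passed, 3514 of them among the 4234, and 9 calls of named genes ended with their differences the same by construction, those of Iyd, Slc26a7, Tshr, Calr, Nkg7, Pecam1, Scgb3a2, Cox5a (adjusted p = 0.0545) and Tek (0.0507). Deviations of same-numbered tumours correlated at 0.03, −0.09, −0.04, −0.07 and 0.12. This gives no sign that the numbers pair the tumours, but pairing was not tested and the labels do not settle it. Detection above background is not given, which limits what can be said of dim genes.

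Among lists that had not passed, single arrays moved the median of the chemokine list to −0.24, of the muscle list to between −0.35 and −0.054 and of the nerve sheath list to between −0.28 and −0.011. Values that turned sign had not passed. Without ATC replicate 2 and PTC replicate 5 they were Mcpt4 (−0.019), Pmp22 (0.13), Sox10 (0.016), Alas2 (0.017), Dusp6 (0.10) and the nerve sheath list (0.016). With the parathyroid covariate, made of Pth and Casr, the value of Pth (0.055) is set by that construction, and the others were the protease list (−0.029) and the neutrophil list (0.047), and with array weights Pmp22 (0.035) and the protease list (−0.027). Quantile normalization gave 0.0073 for Sox10, 0.027 for Alas2, 0.0080 for the neutrophil list and 0.012 for the C cell list, and centring gave 0.010, 0.039, 0.0040 and 0.0018 for them. The Y-linked covariate gave 0.025 for Alas2. Leaving out genes below the median brightness gave −0.045 for the interferon list, 0.27 for the ciliary list and 0.054 for the C cell list, and a milder filter gave 0.12 for the ciliary list. Leaving out single arrays gave ranges of −0.0100 to 0.68 for Mcpt4, −0.28 to 0.11 for Pmp22, −0.077 to 0.0023 for Sox10, −0.061 to 0.094 for Alas2, −0.19 to 0.069 for Dusp6, −0.031 to 0.23 for the interferon list and −0.18 to 0.024 for the neutrophil list. With genes below the median brightness left out, the T cell, natural killer, mast cell, parathyroid, fat and red cell lists had too few members for a test, and with the milder filter the natural killer list.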

Other observations

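The lists in this part, the tests of the macrophage pattern, the comparisons of surfactant and epithelial genes at like brightness and the leaving out of surfactant genes chosen for their fall came after the data were seen; the tests on other splits and on chromosomes and the other tests on surfactant genes were set down before their results were seen. Of 9 oncofetal genes, known mainly from embryonic tissue and tumours, 5 rose and 0 fell (median 0.52), among them the chromatin gene Hmga2 (2.79, adjusted p = 0.000108), the retinoid binding protein gene Crabp1 (2.70, adjusted p = 0.000925), Igf2 (1.88, adjusted p = 0.0254) and Plag1 (1.25, adjusted p = 0.00219). Of 7 granzyme genes 5 rose and 0 fell (median 1.65), with Gzmg at 2.46, Gzmf at 2.43, Gzma at 0.04 and Gzme at −1.61 (adjusted p = 0.169). These granzyme genes are close paralogs, and signal shared between their probe sets was not tested. Of 20 neuronal genes 4 rose and 0 fell (median 0.00), namely Nefm (3.13), Nefl (2.58), Uchl1 (1.31) and Gap43 (0.60), while the synaptic genes Snap25 (0.34) and Syp (0.10) did not pass.

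Of 12 squamous genes 0 rose and 5 fell (median −0.26), with Krt14 at −0.79 and Krt17 at −0.76. Targets of the YAP coactivator had 2 of 12 up, Ankrd1 (2.72) and Axl (1.17), and 2 down, Crim1 (−0.71) and Nuak2 (−0.58), with a median of −0.01. Of 14 genes typical of resident-type macrophages 8 rose and 0 fell (median 1.43), including Vsig4 (4.98), Folr2 (2.14) and Fcna (2.20), while Timd4 (0.12) did not pass. Of 10 monocyte and inflammatory macrophage genes 1 rose, Cd86 (0.70), and 0 fell. With an estimated correlation, 0 of these lists passed (limma camera, adjusted p from 0.153 to 0.941). The lists fixed before the data were seen also held 2 of the resident-type, 3 of the monocyte, 2 of the granzyme and 1 each of the YAP and squamous genes. Vsig4, Cd163, Lyve1 and F13a1 entered the resident-type list after their rises were seen, and of the other 10 members 4 rose, with a median of 0.63. Nefm entered the neuronal list likewise, and 3 of the other 19 members rose.

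Of the 14 macrophage markers 13 rose in ATC (median 1.34, adjusted p = 0.134 with an estimated correlation). A lower epithelial share would raise the markers of every other cell type alike, but among the fibroblast, endothelial, T cell and B cell lists the highest median was −0.18. More myeloid cells of every kind is argued against by the neutrophil list, whose median lay 1.38 below the macrophage median. The 95% bootstrap interval of that gap was 1.00 to 2.25, and 0.80 to 3.19 for genes above the median brightness. The brighter neutrophil genes were only 6 and include Lcn2, whose cell source was not tested. Set against the PTC mean, the neutrophil median lay at least 0.79 below the macrophage median in each ATC tumour. Bootstrap intervals in this paragraph resample genes and not tumours. More monocytes or mast cells stay open: the monocyte median was 0.025, but for its 6 genes above the median brightness it lay 0.79 below the macrophage median (0.27 to 2.02), and the mast cell list, with 3 of 8 up, had a median of 0.25 (0.39 to 1.34 below; adjusted p = 0.379 with an estimated correlation). More macrophages, or a change of state in those present, may also account for the rise, and these data do not separate the 2; tumour type and p53 genotype also stay open, untested.

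Genes listed for lung surfactant and airway secretion were mostly high in PTC, but Scgb3a2 was at 6.73 there. Of 18, 17 fell in ATC and 0 rose (median −2.85, camera adjusted p = 0.153 with an estimated correlation). Without 5 genes chosen for their fall, 12 of 13 fell, with a median of −2.58. Among those that fell were Sftpb (11.93 ± 0.34 to 9.27 ± 1.66), Sftpd (11.10 ± 0.16 to 8.36 ± 1.29) and Napsa (11.25 ± 0.33 to 8.68 ± 1.18). The list also holds Lrp2 (−3.13) and Ager (−1.78), and whether their falls belong to the same pattern was not tested. Lung or airway tissue in the PTC pieces is argued against by 12 abundant lung and airway transcripts, with 0 up, 2 down (Bpifa1 at −2.51 and Aqp5 at −0.52) and a median of −0.21; Sftpc was at 6.64 ± 0.57 in PTC. Lamp3, Cxcl15, Cyp2f2, Chil1 and Dcpp3 entered the list after their falls were seen, and without them the medians of the 2 lists differed by 1.77 to 2.77 (95% bootstrap interval). The bootstrap intervals in this paragraph resample genes and not tumours. A larger epithelial share alone stays open. The list mean, with the 5 genes chosen for their fall included, fell by 1.26 more than the epithelial list mean. Those 5 genes enlarge that gap, and dim epithelial genes dilute the epithelial mean. Without those 5 genes, the members with a PTC mean above 9 had medians of −2.62 (10 surfactant genes) and −2.11 (12 epithelial genes). The difference was −0.51 (95% bootstrap interval −0.91 to 0.19). Against the epithelial gene nearest in PTC mean, the difference without those 5 genes was −0.64 (exact permutation test, two-sided p = 0.0238). Expression of these genes by the papillary tumour cells, which share the factor Nkx2-1 with lung epithelium, may also account for the pattern as a hypothesis, and cross-hybridisation among the 3 Dcpp genes was not tested.

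Neighbouring genes shifted together in the ATC tumours. Over the 9642 genes above the median brightness on 19 autosomes, the spread of chromosome means was taken relative to 200 shuffles of gene positions. Each tumour was set against the mean of the other tumours of its type. This ratio was 4.33 ± 0.85 in ATC and 2.00 ± 0.54 in PTC, a difference of 2.33 (permutation of the finished ratios, two-sided p = 0.00794, the smallest it can give). Ratios within a type share their reference tumours and so depend on each other. They were not recomputed in each permutation, so this p is approximate. Against the PTC mean, chromosome 3 averaged 0.36, 0.23 and 0.19 in ATC replicates 3, 5 and 4 but 0.11 and 0.03 in ATC replicates 2 and 1, and in ATC replicate 3 the shift was present in its first, middle and last parts (0.31, 0.42 and 0.37). The other autosomes averaged 0.024, 0.097 and −0.021 in ATC replicates 3, 5 and 4, and 77.5%, 72.9% and 73.5% of chromosome 3 genes lay above their PTC mean, against 56.8%, 62.4% and 51.4% on the other autosomes. Of the chromosome 3 genes 33.8% rose, against 18.9% elsewhere, while chromosome 13 was low in ATC replicate 4 (−0.22) and chromosome 8 in ATC replicate 1 (−0.21). Gains and losses of whole chromosomes may account for this; DNA copy number was not measured, and shared regulation of neighbouring genes was not tested.

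Other splits of the 10 tumours into 5 and 5 were counted for the main results, with 100 of the 126 possible splits drawn. Only the real split, 1 of 100, gave 4234 genes past the threshold, and the highest of the others gave 5. A count this large is thus unlikely by chance, at 1 of 100, the smallest share that these splits can give. The other splits mix the types, which adds the real difference to the spread within groups and lowers their counts. For the 850 genes that also differed by 1 log2 unit it was again 1 of 100, with 5 the highest of the others. For the number of lists past the camera test with its preset correlation, 17 of 100 splits gave at least the real 13 and the highest of the others gave 17. The split with 17 exchanged only 1 tumour of each type, so it kept most of the real difference. Splits that exchanged 2 tumours of each type, the most even mixture, also reached 14 or 15 lists, with 0 genes past the threshold. The number of lists past camera at its preset correlation is therefore no evidence against chance, and chance is not excluded for that number.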
